A study of Mus musculus with 4 samples.

How the data were processed

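Total RNA from whole pancreas of adult mice was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The series holds 4 arrays: 2 from wild-type mice and 2 from Ifrd1 null mice, each taken on day 5 of a cerulein course. The values used here are the authors' deposited values per array and transcript cluster, treated as log2 expression levels. Neither the log base nor the background correction, probe summary and normalization method is given in the sources used here. The log2 scale was inferred from the values, which lay between 0.218 and 13.9, so every fold change below rests on that reading. The array medians were 4.11 and 4.08 for wild type 1 and 2 and 4.15 and 4.13 for Ifrd1 null 1 and 2, so the arrays had been brought close to a common level before deposit.

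The table had 41345 rows. The annotation of the array platform gave 1 gene symbol for 23521 rows and several symbols for 1814 rows, and 16010 rows were without a symbol here. Only rows with 1 symbol were used for genes, and a gene with more than 1 row (1082 genes) was represented by the row with the highest mean over the 4 arrays, which left 22180 genes. Gene identifiers were looked up in a RefSeq gene table of assembly GRCm38.p6, which held 21994 of them and missed 186. That table served for names, chromosome assignment, the order of neighbouring genes and which gene lies within another, and no coordinates from it are given. No filter on dim rows was applied, and no detection call was used, so a level below the array median is not shown to be above background. No value column belonged to a sample outside the 4 arrays.

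Groups were compared with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, without covariates, as Ifrd1 null minus wild type. P-values were two-sided and adjusted over all genes by Benjamini-Hochberg, with a threshold of 0.05. Errors of differences are limma's moderated standard errors (SE), and errors of group means are standard deviations (SD). With 2 arrays against 2, an exact permutation test of a single gene cannot go below p = 0.333, so no such test is reported. The number of arrays limits the precision of every value. The labels call the samples biological replicates without stating the sex, litter or day of each mouse.

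The choices of test, samples, gene lists and named genes were made before the data were examined. Lists with at least 5 measured members were tested with camera, which compares the members' shift with that of all other genes, at its preset correlation between genes of 0.01, and adjusted over the 26 lists tested. The same lists were tested with camera at a correlation estimated per list and with fry, which asks whether the members move one way on balance. Of 649 symbols on the lists, 587 were measured, 3 of them through a synonym. Each list median was also set against 10000 random lists of the same size matched on mean expression in 50 bins. Their members were drawn independently, so the percentiles take no account of correlation between list members or of variation between mice. The same holds for the gene sets added later. A further list of sex-linked genes served as a check of the samples and was not tested.

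Named genes follow a fixed rule: Ifrd1 and its paralog Ifrd2; the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap, filled up to 10 with the genes of smallest unadjusted p whose groups do not overlap and whose absolute log2 difference was at least 0.58; of each list, the member with the highest mean and the pair of members with the smallest unadjusted p; and Ddit4, Cdkn1a, Mki67 and Mtor. Genes without a named function, RNA genes and immunoglobulin or T cell receptor segments were skipped in the second part, which passed over 7 rises and 0 falls. The rule also names Trp53, which is not analysed here. The rule takes 100 entries in all, and the text gives the ones that bear on each comparison. Genes outside the rule are said to have been chosen after their values were seen.

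The gene and list tests were tested on simulated data built from these 22180 genes, with 200 genes changed in each of 20 runs. At adjusted p under 0.05, limma recovered 0.1% of genes changed by 0.5 on the log2 scale, 2.8% at 1, 75.1% at 2 and 95.8% at 4. False calls made up 4.61% of all calls. A shifted list was called in 20 of 20 runs, and other lists were called 1 time. Simulated genes varied independently of each other, so these list rates do not carry over to lists whose members vary together. Changes of 2-fold or less were thus mostly out of reach of the single-gene test. The 200 changed genes per run ease the Benjamini-Hochberg cutoff, so recovery can be lower where few genes change strongly. In the data, Ifrd1 (-2.02) missed the threshold, as did Kdm5d, Eif2s3y and Xist with larger differences (limma adjusted p from 0.138 to 0.140).

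Alternatives were quantile normalization applied again, median centring of arrays, the replicate number as a block, the mean of all rows of a gene, genes above the median level, eBayes with a trend and with trend and robust, all rows without collapsing, other thresholds, lists without shared genes, the other list tests, and leaving out each array in turn. Cyclic loess, removal of genes annotated to X or Y and removal of genes holding identical values in more than 1 array were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.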

Results

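Gene expression was measured on Affymetrix arrays in the pancreas of 8-week-old mice on day 5 of a cerulein course. Cerulein is an analog of cholecystokinin that over-stimulates the enzyme-secreting acinar cells and causes acute pancreatitis, and it was given at 100 µg/kg, in 6 injections per day on alternate days. The study took tissue at a stage when the injured pancreas proliferates. It compared wild-type mice (n = 2) with mice null for Ifrd1 (n = 2), a gene for a transcriptional co-regulator. Untreated pancreas is not analysed here, so all values compare genotypes within injured tissue. Over 22180 genes, pairs of arrays correlated with r between 0.986 and 0.991 (Pearson, across genes, which are not independent replicates). The closest pair was wild type 1 with wild type 2, and the least alike were the Ifrd1 null arrays.

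The Ifrd1 transcript was 4.05-fold lower in the null arrays. Its level was 9.06 ± 0.02 in wild type and 7.04 ± 0.07 in the null (log2, SD, n = 2 each), a difference of -2.02 ± 0.11 (SE). All 4 arrays matched their labels, with 9.04 and 9.07 in wild type against 6.99 and 7.09 in the null. The probes of this transcript cluster still gave a signal above the array median in the null, and whether they lie in the deleted part is not given in the sources used here. The limma adjusted p over all genes was 0.138, so Ifrd1 itself did not pass the threshold, and it was 0.031 with arrays centred on their medians, 0.042 with a trend and robust eBayes and 0.021 without genes holding identical values. Its paralog Ifrd2 stood at 8.22 ± 0.05 in wild type and 8.14 ± 0.55 in the null (SD), a difference of -0.08 ± 0.28 (SE) whose sign turned with cyclic loess (0.01).

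The genotype groups also differed in sex-linked genes. Xist, the RNA that silences an X chromosome in female cells, was at 2.56 and 3.54 in the wild-type arrays and at 10.2 and 9.58 in the null arrays, a difference of at least 6.82 ± 0.39 (log2, SE). The Y-linked genes went the other way: Uty was lower in the null by at least 4.10 ± 0.11, Eif2s3y by at least 4.01 ± 0.22 and Kdm5d by at least 2.97 ± 0.16. The dim group of each of these 4 genes lay below the array median, where signal above background is not shown, so the differences are lower bounds. The sex of the mice is not stated in the labels. By these genes the null arrays read as female and the wild-type arrays as male. In these 4 arrays a genotype difference is therefore also a difference in sex as read from these genes, and the design cannot separate the 2.

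**Figure D1:**
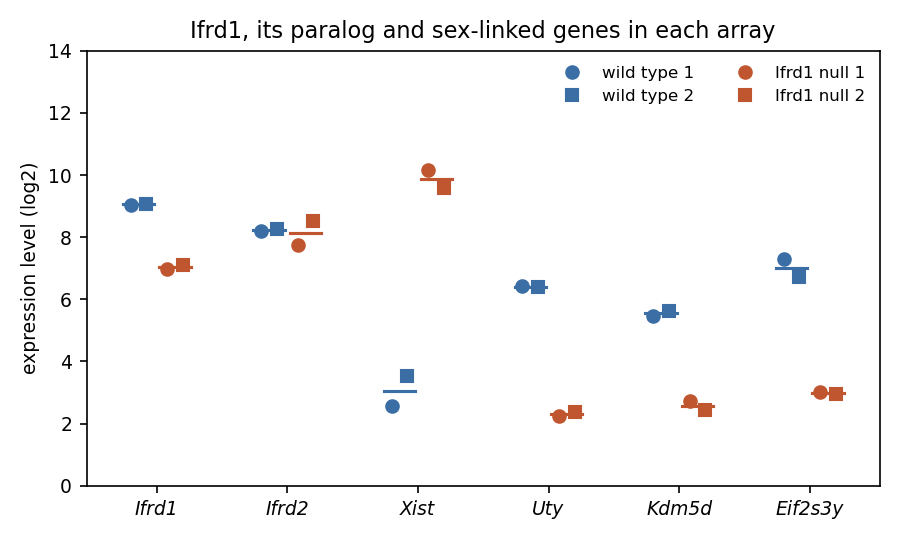
Expression level (log2) of Ifrd1, Ifrd2, Xist and 3 Y-linked genes in each of the 4 arrays; circles are replicate 1, squares replicate 2, and horizontal bars the mean of each genotype. Ifrd1 is 1.95 log2 units or more lower in each null array, and Xist and the Y-linked genes separate the genotypes as well.

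Across the transcriptome, 1 gene passed the adjusted threshold, Uty, which fell by at least 4.10 on the log2 scale (limma adjusted p = 0.0206, lower in both null arrays). No gene rose past it (0 genes). At unadjusted p under 0.05 there were 1532 genes, 726 higher and 806 lower in the null, against 1109 expected by chance. With quantile normalization there were 1200, with cyclic loess 1192 and with arrays centred on their medians 1554. Most of the excess was thus absent with quantile normalization and cyclic loess, but not with median centring. Groups did not overlap for 35.8% of genes, where chance gives 33.3%. With genes annotated to X or Y left out, 0 genes passed in limma and 1456 had unadjusted p under 0.05. At adjusted p under 0.15 there were 5 genes, which were Uty, Ifrd1, Kdm5d, Eif2s3y and Xist.

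The remaining genes named by the rule did not pass. The autosomal gene nearest to the threshold after Ifrd1 was C7, which encodes complement component 7. It was 3.07-fold lower in the null (7.55 ± 0.13 against 5.93 ± 0.04, SD; difference -1.62 ± 0.12, SE; limma adjusted p = 0.318). The lower genes further held Gpx2, a glutathione peroxidase of epithelia, at -1.21 ± 0.16, Rec8, a meiotic cohesin subunit, at -1.02 ± 0.15, Hsd3b3 at -0.93 ± 0.12, Olfr192 at -0.94 ± 0.12 and Pla1a, a phospholipase, at -0.85 ± 0.10 (log2, SE). Among the higher genes were Fkbp5, a glucocorticoid-induced co-chaperone of steroid receptors, at 0.95 ± 0.11, and Zbtb16, a transcription factor, at 0.91 ± 0.13. Pik3c2g stood at 0.75 ± 0.12, P2rx6 at 0.68 ± 0.11, Tdrd1 at 0.78 ± 0.12 and Ssxa1 at 0.71 ± 0.11. The olfactory receptor genes Olfr601 (0.93 ± 0.12), Olfr765 (0.78 ± 0.10) and Olfr1061 (0.78 ± 0.10) were among the higher genes too. Levels were low, below the median of every array, for these 3 and for Olfr192, Hsd3b3, Ssxa1 and Tdrd1, and Gpx2 was below it in 3 of 4 arrays and P2rx6 in the 2 wild-type arrays, so none of these differences is exact. Each of these had a limma adjusted p of 0.721 apart from C7.

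Gene lists showed smaller shifts that ran over many members. Of all genes 47.2% were higher in the null, and of genes above the median level 32.6%. A list of bright genes is thus likely to hold more lower than higher members. Of 26 lists, 8 passed camera at the preset correlation, 6 lower and 2 higher in the null. With an estimated correlation 0 lists passed (adjusted p from 0.516 to 0.916), and by fry 0 passed. With an estimated correlation camera uses only the residual degrees of freedom, few with 4 arrays, so a list could hardly pass. DNA replication genes missed it with an estimated correlation of 0.0145, close to the preset 0.01. A miss in that test therefore does not show that correlation between members made a call. Against random lists matched on expression, 14 of the 26 medians lay outside the central 95%, 6 of lists past camera and 8 of lists not past it. The mTORC1 and endothelial lists passed camera with medians inside that range. The range ignores correlation between members, so a median outside it is not a test against variation between mice. No member of the 8 lists past camera passed over all genes or adjusted over the list alone (0 genes in each).

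Targets of p53, the transcription factor of the DNA damage response, had the largest shift. Their median was -0.34 (1.26-fold lower), and 24 of 26 measured members were lower in the null, 11 of them at unadjusted p under 0.05. Psrc1, a microtubule regulator, was at -0.79 ± 0.16, Sesn2, a stress-induced inhibitor of mTORC1, at -0.79 ± 0.20, Eda2r at -0.54 ± 0.11, Btg2, an antiproliferative gene, at -0.56 ± 0.11 and Ccng1, the member with the highest level, at -0.45 ± 0.13 (log2, SE). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, was at -0.25 ± 0.14, and Ddit4, an mTORC1 inhibitor, was at 0.02 ± 0.10, a sign that turned with arrays centred on their medians (-0.03). Camera gave an adjusted p of 1.59e-07 at the preset correlation, and adjusted p = 0.516 with an estimated correlation. The list median lay below all 10000 matched random lists, which ignore correlation between members. The median stayed below 0 with each array left out in turn, from -0.40 without wild type 1 to -0.21 without wild type 2.

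DNA replication genes were lower as well, with a median of -0.18 and 23 of 27 members lower. Mcm5 (-0.56 ± 0.13) and Mcm7 (-0.47 ± 0.11), subunits of the replicative helicase, had the smallest unadjusted p of the list, and Pcna, the sliding clamp, was at -0.10 ± 0.11. The camera adjusted p was 1.48e-04, and adjusted p = 0.516 with an estimated correlation. The list median stayed below 0 with each array left out in turn (-0.17 to -0.13). Over all arrays it lay at percentile 0.01 of matched random lists. Mitosis genes did not pass (median -0.04, 19 of 29 lower, camera adjusted p = 0.276). Within that list Cdk1 was at -0.49 ± 0.14 and Ttk at -0.56 ± 0.18. Ttk lay below the array median in 3 of 4 arrays, so its difference is not exact. Mki67, the common marker of cycling cells, was at -0.02 ± 0.13, a sign that turned with quantile normalization (0.05).

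**Figure D2:**
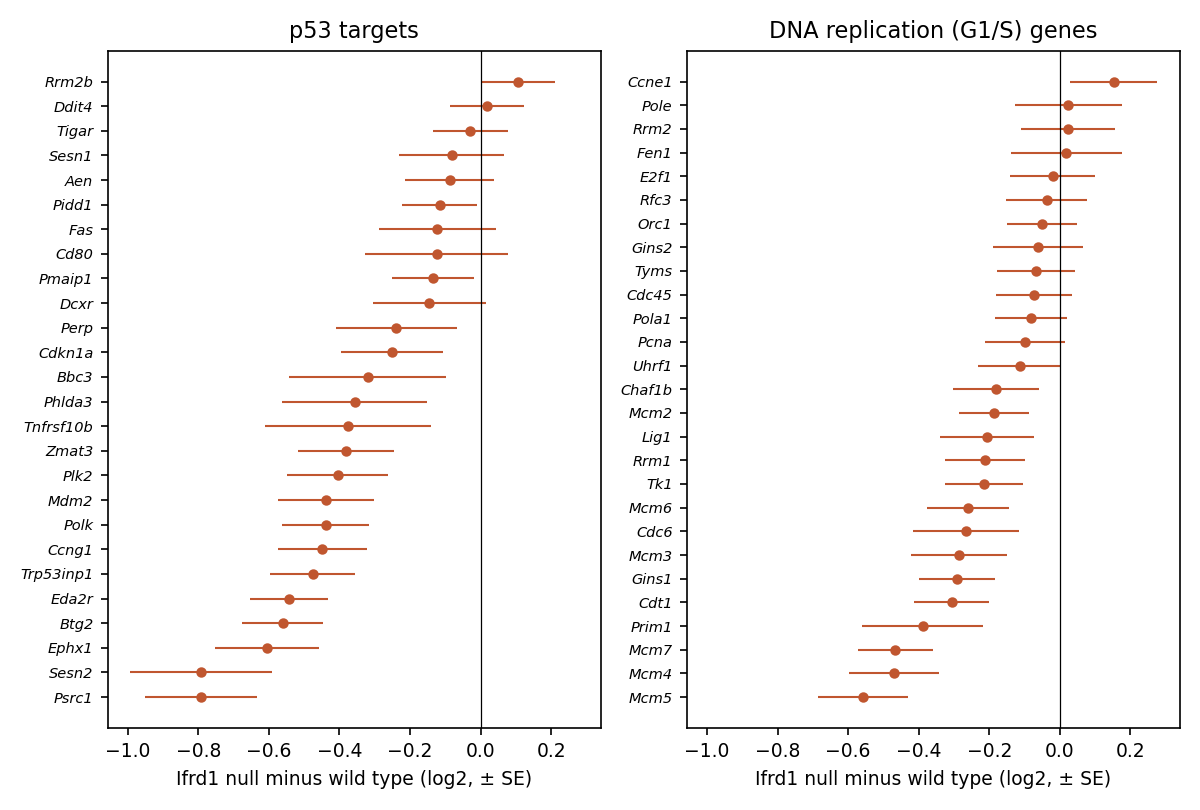
Difference between Ifrd1 null and wild type (log2, horizontal axis) for each measured p53 target and each DNA replication gene; points are limma estimates and bars 1 standard error, n = 2 arrays per group. In all, 24 of 26 p53 targets and 23 of 27 replication genes lie below 0.

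Markers of duct cells and of acinar-to-duct metaplasia had a median of -0.15, with 23 of 29 lower. Krt19, a duct keratin, was at -0.59 ± 0.12 and Itgb4, a laminin receptor subunit, at -0.49 ± 0.11, while Clu, the member with the highest level, was at -0.03 ± 0.10, a sign that turned with quantile normalization (0.005) and cyclic loess (0.02). The camera adjusted p was 3.94e-04, and adjusted p = 0.516 with an estimated correlation. Wild type 1 carried intestinal transcripts that were far lower in the other arrays. Among them was the list member Agr2 (6.06, at least 2.06 above the next array, chosen after its values were seen). Without wild type 1 the duct median was -0.23 and without Ifrd1 null 1 it was -0.40 (adjusted p = 0.00636 and 0.00448). Among genes above the median level the list did not pass (adjusted p = 0.052), and its median over all genes lay at percentile 1.28 of matched random lists. The intestinal epithelium list did not pass (median -0.07, camera adjusted p = 0.732), and its median without wild type 1 was 0.08. Vil1 was at -0.97 ± 0.25, Slc5a1 at -0.59 ± 0.17 and Anpep, the member with the highest level, at 0.16 ± 0.15. Vil1 lay below the array median in Ifrd1 null 1, so its difference is not exact.

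Components and regulators of mTORC1, the growth-control kinase complex, had a median of -0.10, with 22 of 29 lower. The list holds both subunits and inhibitors of the complex, so its median gives no direction of mTORC1 activity. Sesn2, an inhibitor shared with the p53 targets, was at -0.79 ± 0.20. Mlst8, a subunit, was at -0.39 ± 0.10, Mtor itself at -0.04 ± 0.10 and Rps6, a ribosomal protein with the highest level of the list, at 0.00 ± 0.10; the signs of Mtor and Rps6 turned with cyclic loess (0.04 and 0.05). The camera adjusted p was 0.0191, and adjusted p = 0.912 with an estimated correlation. The list median lay at percentile 24.0 of matched random lists, inside their central 95% (-0.14 to -0.0053). The call ended with quantile normalization (adjusted p = 0.251), with cyclic loess (0.308), among genes above the median level (0.406), without wild type 2 (median -0.03) and without Ifrd1 null 1 (median -0.06), while the median was -0.16 without wild type 1.

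T and NK cell markers were higher in the null, with a median of 0.27 and 18 of 19 members higher. Nkg7, a granule protein of cytotoxic lymphocytes, was at 0.49 ± 0.11 and Lat, an adaptor of the T cell receptor, at 0.57 ± 0.14, while Cd4 stood at 0.27 ± 0.40. Lat lay below the array median in both wild-type arrays, so its difference is not exact. Interferon response genes had a median of 0.24, with 13 of 19 higher. Irf7, a regulator of type I interferon, was at 0.65 ± 0.11, Oas2, an antiviral synthetase, at 1.04 ± 0.25 and Bst2 at 0.39 ± 0.14. Camera gave adjusted p = 5.14e-05 and 0.00188, and for both lists adjusted p = 0.516 with an estimated correlation. Both medians lay at percentile 100 of matched random lists, which ignore correlation between members. Without Ifrd1 null 1 neither passed (medians 0.13 and 0.08, adjusted p = 0.104 and 0.0777), and the interferon list also missed the threshold without wild type 1 (0.0808) and without wild type 2 (0.0577); its median was 0.40 without Ifrd1 null 2. Against the wild-type mean, T and NK markers were at 0.40 in Ifrd1 null 1 and 0.13 in Ifrd1 null 2. Other cell types were higher in that first array too: B and plasma cell markers had medians of 0.69 and -0.42, adipocyte markers 0.57 and -0.31 and macrophage markers 0.31 and -0.34. A different mix of cells in that sample is not separated from genotype here.

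Markers of stellate cells, fibroblasts and matrix had a median of -0.20, with 21 of 27 lower. Mmp14, a membrane-bound matrix protease, was at -0.46 ± 0.15 and Bgn, a matrix proteoglycan, at -0.19 ± 0.15, while Timp1, a protease inhibitor, was at 0.42 ± 0.11. Endothelial markers had a median of -0.12, with 13 of 16 lower, Plvap at -0.60 ± 0.15 and Emcn at -0.36 ± 0.10; Lyve1 was at -0.02 ± 0.33, a sign that turned with quantile normalization (0.05) and cyclic loess (0.07). Camera gave adjusted p = 0.0183 for each, and adjusted p = 0.912 for stellate and 0.516 for endothelial markers with an estimated correlation. The stellate median lay at percentile 0.06 of matched random lists, and the endothelial median at percentile 7.37, inside their central 95% (-0.14 to 0.05). The stellate shift was carried by Ifrd1 null 2: without it the median was -0.0025, without Ifrd1 null 1 it was -0.44, and the call also ended without wild type 1 (-0.12), with quantile normalization (adjusted p = 0.105), with cyclic loess (0.225) and among genes above the median level (0.406). In Ifrd1 null 2 the markers of macrophages, B and plasma cells and adipocytes were lower than the wild-type mean as well (-0.34, -0.42 and -0.31) and digestive enzymes higher (0.24), so the stellate values went along with those of other cell types in 1 array. The endothelial median was -0.23 without Ifrd1 null 1 and -0.21 without wild type 1 (adjusted p = 0.00235 and 0.0483), and the call ended without wild type 2 (-0.11), without Ifrd1 null 2 (-0.11) and among genes above the median level (adjusted p = 0.124).

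**Figure D3:**
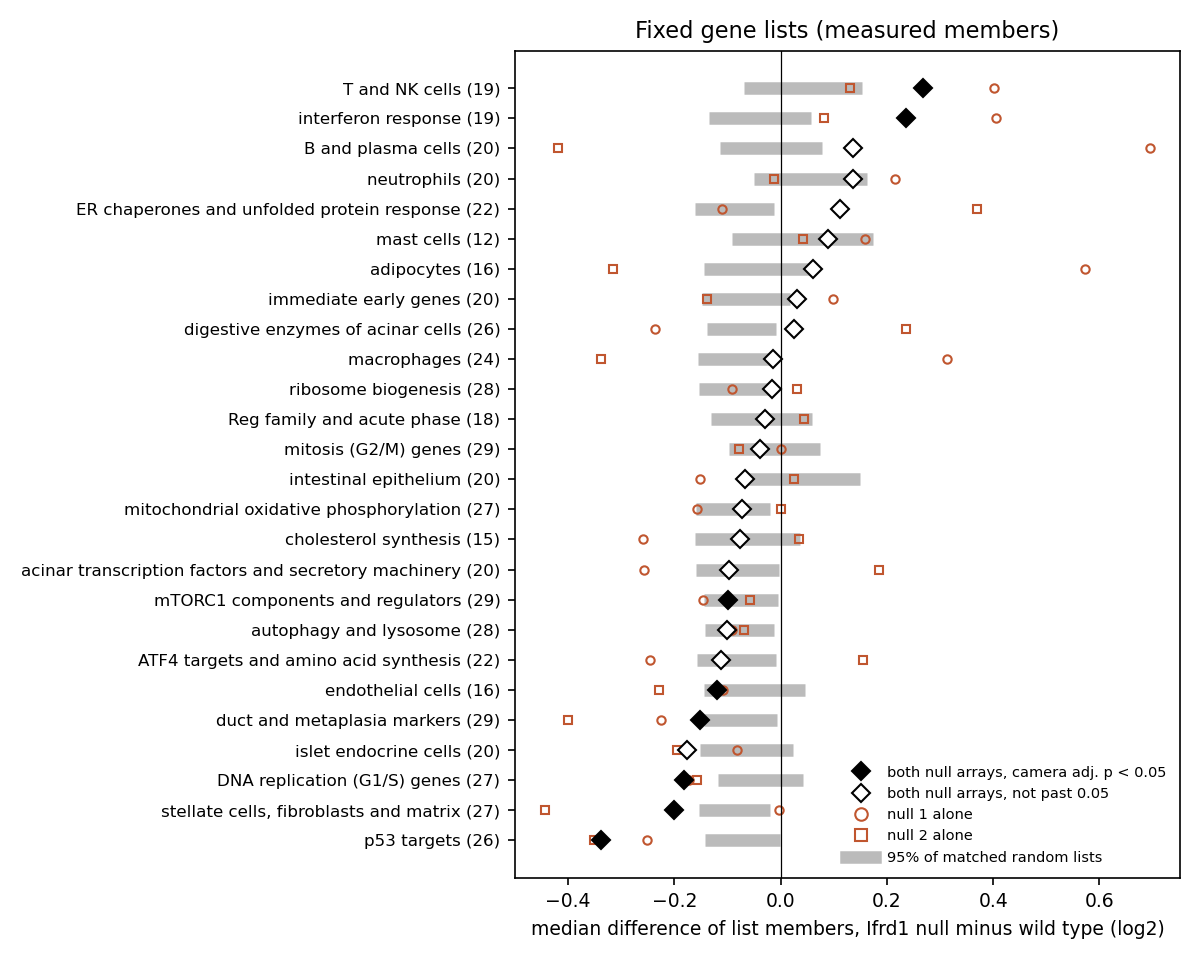
Median difference between Ifrd1 null and wild type (log2, horizontal axis) over the measured members of each of 26 gene lists, member numbers in brackets; diamonds use both null arrays and are filled where camera passed at its preset correlation, open circles and squares use Ifrd1 null 1 or 2 alone against the wild-type mean, and grey bars hold 95% of matched random lists. The p53 targets lie furthest below 0, and the null arrays fall on opposite sides of 0 for B and plasma cells, adipocytes, macrophages and digestive enzymes.

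Acinar cell genes did not pass over all arrays and genes. Digestive enzymes had a median of 0.02 (16 of 26 higher, camera adjusted p = 0.411; 0.0357 among genes above the median level, with a median of 0.018), with Try4 at 0.14 ± 0.11 and Prss1 at 0.19 ± 0.12. Ctrb1 was the brightest row of every array (13.9 in each), so its difference cannot be read. The null arrays differed by a median of 0.139 over the 9 enzymes with a mean above 13 and by 0.717 over the other 17 (absolute log2, chosen after the values were seen). The scale may be compressed near that top, which was not tested. The enzyme medians may therefore give little on the brightest members. The median difference between genotypes was 0.07 over those 17, with 12 higher. Acinar transcription factors and secretory machinery had a median of -0.10 (adjusted p = 0.553), with the cholecystokinin receptor Cckar at -0.16 ± 0.19, Gata4 at -0.30 ± 0.21 and Gnmt at 0.65 ± 0.43. The null arrays stood apart here: null 1 minus null 2 had a median of -0.56 for digestive enzymes and -0.57 for the acinar factors, and 0.65, 1.17 and 0.62 for macrophages, B and plasma cells and adipocytes. Without Ifrd1 null 2 the enzyme median was -0.24 and that of the acinar factors -0.26, and without Ifrd1 null 1 they were 0.24 and 0.19, each past the threshold at the preset correlation; over all arrays both lists had adjusted p = 0.912 with an estimated correlation.

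Other lists did not pass over all arrays and genes. Islet endocrine genes had a median of -0.18 (13 of 20 lower, camera adjusted p = 0.0664; median -0.08 without Ifrd1 null 2), with G6pc2 at -0.74 ± 0.16 and Iapp at -0.65 ± 0.15, both beta cell genes, and glucagon, Gcg, at 0.24 ± 0.12. ER chaperones had a median of 0.11 (camera adjusted p = 0.1001), with Dnajb9 at 0.37 ± 0.12. Dnajb9 is 1 of the 100 genes nearest to Ifrd1 in gene order. The ER list passed with quantile normalization (0.00871), with cyclic loess (0.00145) and among genes above the median level (0.00158). Its median was 0.37 without Ifrd1 null 1 and -0.11 without Ifrd1 null 2. Over all arrays the list had adjusted p = 0.912 with an estimated correlation. ATF4 targets had a median of -0.11 (0.191), autophagy and lysosome genes -0.10 (0.0772, Sqstm1 at -0.33 ± 0.14), cholesterol synthesis -0.08 (0.226) and oxidative phosphorylation -0.07 (0.167). Without Ifrd1 null 2 the ATF4, cholesterol and oxidative phosphorylation lists passed, with medians of -0.24, -0.26 and -0.16; over all arrays each had adjusted p = 0.912 with an estimated correlation. Ribosome biogenesis had a median of -0.02 (0.782, Ncl at -0.32 ± 0.11, Npm1 at 0.07 ± 0.13 and turning to -0.07 with the mean of its rows), and the Reg family and acute phase genes -0.03 (0.789, Reg1, also at a level above 13, at 0.05 ± 0.10, Cp at -0.37 ± 0.12).

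Neutrophil markers had a median of 0.14 (camera adjusted p = 0.0772), and passed with arrays centred on their medians (0.0382), without wild type 1 (0.0483) and without Ifrd1 null 2 (0.00699), but not without Ifrd1 null 1 (median -0.01); over all arrays the adjusted p was 0.823 with an estimated correlation. Their members included Retnlg at 1.11 ± 0.27 and Csf3r at 0.00 ± 0.10, the second of which turned to -0.05 with arrays centred on their medians. Macrophage markers had a median of -0.02 (0.479), with Cd14 at -0.44 ± 0.10 and Lyz2 at -0.35 ± 0.29. B and plasma cell markers had a median of 0.14 (0.268), with Ighm at -0.61 ± 1.19, and adipocyte markers one of 0.06 (0.599), with Car3 at -0.22 ± 0.70. Those 3 lists passed in opposite directions without Ifrd1 null 1 (medians -0.34, -0.42 and -0.31) and without Ifrd1 null 2 (0.31, 0.69 and 0.57). These calls used the preset correlation of 0.01, while the correlations estimated over all arrays were 0.894, 0.671 and 0.865, and each list had adjusted p = 0.912 with an estimated correlation. Mast cell markers had a median of 0.09 (0.479), and 1 member passed when adjusted over the list alone, Kit, at -0.60 ± 0.11, against 0 over all genes. Immediate early genes had a median of 0.03 with a mean of -0.06 (0.732, test direction lower); Jun was at -0.59 ± 0.11 and Myc at 0.18 ± 0.12.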

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

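The tests of a swap of arrays, of the share of duct-like cells, of the sex of the mice for the p53 targets, of intestinal tissue for the p53 targets and of array noise were chosen only after the result was seen.

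Rows outside the gene table held signals that followed the groups. Of 17824 such rows, 5 without a gene name here were higher in both null arrays than in both wild-type arrays by a gap of over 2 log2 units. Row 17550478 differed by at least 7.33 (null minus wild type), row 17549080 by at least 5.82 and row 17549054 by at least 5.78. Row 17550444 differed by at least 5.75 and row 17549096 by at least 5.33. Their wild-type values lay below the array medians, where signal above background is not shown, so these are lower bounds. In the opposite direction 1 row had the same gap. The 5 rows were dim and bright in the same arrays as Xist, so sex and genotype cannot be told apart for them.

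Xist and the Y-linked genes separated the genotype groups. Mice of opposite sex in the groups predict higher levels of genes that escape X inactivation: 5 measured escape genes had a median of 0.30, at percentile 99.99 of matched random lists, with Kdm6a at 0.37 ± 0.11 and Utp14a at -0.01 ± 0.15 (log2, SE; chosen after values were seen), while 893 other X-linked genes had a median of 0.02. A swap of arrays between the groups is argued against by Ifrd1, whose lowest wild-type value lay 1.95 log2 units above the highest null value. Female null and male wild-type mice are thus a candidate explanation, and genotype and sex stay confounded for every gene.

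The p53 target list was lower in the null arrays. An intensity-dependent trend between arrays, seen as a median difference from 0.09 in the fourth expression decile to -0.10 in the tenth, is argued against as the whole cause, since the list median lay at percentile 0 of lists matched on expression (lower bound of these -0.14). Intestinal tissue in wild type replicate 1 is argued against, since the median without that array was -0.400, against -0.34 with all arrays. The list still passed camera without that array. That call used the preset correlation and left wild type 2 alone in its group, so it does not measure variation between mice. A lower share of duct-like cells stays open, with a duct median 0.186 above the p53 median (bootstrap interval -0.201 to 0.288). The bootstrap resampled list members, not arrays, so its interval does not cover variation between mice. The sex of the mice cannot be told apart from genotype, since 0 groups hold both sexes by Xist. Loss of Ifrd1 remains a hypothesis beside these, and the call was absent with an estimated correlation (adjusted p = 0.516).

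Intestinal genes were higher in wild type 1 than in the other arrays. The gap to the next array exceeded 1.5 log2 units for 22 genes, against 0 genes in wild type 2, 12 in Ifrd1 null 1 and 1 in Ifrd1 null 2. The 22 were led by Lypd8 (at least 5.69), Muc13 (at least 4.90), Muc3 (at least 4.43) and Clca1 (3.52), all chosen after their values were seen. For Lypd8, Muc13 and Muc3 the next array lay below its median, where signal above background is not shown. Intestinal tissue in that sample is a candidate source: 14 colon genes, fixed before they were looked at and 3 of them among the 22, had a median of 0.743 above the other arrays, at percentile 100 of matched random lists (0.53, also at 100, for the other 11). Noise of that array is argued against as the cause by the same 0.743, since random lists from the same differences reached 0.09 at their upper bound. This is the same comparison as for intestinal tissue, so it adds no further evidence. The SD of differences from the null arrays was larger for wild type 1 than for wild type 2 (0.327 and 0.325 against 0.308 and 0.317). These SDs include the intestinal genes, so they do not measure noise alone. No biological explanation was tested, as the design gives none for a single array.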

How the results depend on the processing

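Cyclic loess, removal of X and Y genes and removal of identical values were chosen after seeing the data, and the cause of a change was not tested unless stated. The Ifrd1 difference kept its sign throughout and passed at -2.07 with arrays centred on their medians and at -2.02 with trend and robust eBayes or without genes holding identical values. The count of changed genes, 1 in the report, was 4 with quantile normalization, with cyclic loess and with the replicate block, 5 with median centring, with trend and robust eBayes and without identical values (3124 genes hold one, 46 of them in all 4 arrays), 0 among genes above the median level, over all rows, without X and Y genes, and 0 to 0 with an array left out. Genes at unadjusted p under 0.05, 1532 in the report, were 1200 with quantile normalization, 1192 with cyclic loess, 1554 with arrays centred on their medians and 1218 with the replicate block. Every called gene was Xist, Uty, Kdm5d, Eif2s3y or Ifrd1. Replicate numbers did not pair the samples (r = -0.035 across genes, 2 pairs), and the 4 genes of the paired fit were Xist, Uty, Kdm5d and Eif2s3y. The paired fit also passed the neutrophil (camera adjusted p = 0.0271) and islet (0.0326) lists at the preset correlation, and ended no list call. Without the block, both lists had adjusted p = 0.823 with camera at an estimated correlation. The count of shifted lists, 8 in the report, was 5 among genes above the median level, 0 with an estimated correlation, 0 by fry, and 5 to 15 with an array left out. Median centring moved the share of genes that were higher from 47.2% to 37.7%. Of 1354 values of named genes under alternatives 37 reversed (19 genes), and of 413 list values 32 reversed in the direction of camera's test (16 lists). With quantile normalization Clu was at 0.00464, Mki67 at 0.049, Lyve1 at 0.053 and Mtor at 0.028; with median centring Ctrb1 (the brightest row of every array, so not readable) was at -0.031, Csf3r at -0.048 and Ddit4 at -0.032; with the mean of all rows Npm1 was at -0.070; with cyclic loess Ifrd2 was at 0.010, Clu at 0.015, Mki67 at 0.057, Rps6 at 0.050, Lyve1 at 0.069 and Mtor at 0.035. List medians whose test direction turned were, with quantile normalization, acinar transcription factors -0.065 and ribosome biogenesis 0.019; among genes above the median level, acinar transcription factors -0.096, mitosis -0.023, ribosome biogenesis -0.016, immediate early genes -0.083 and macrophages -0.015; with cyclic loess, acinar transcription factors -0.045, ribosome biogenesis 0.019, oxidative phosphorylation 0.019, immediate early genes 0.10 and macrophages 0.066. With an array left out, a lone array being assumed to vary like the other group, these genes changed sign: Ifrd2 (-0.47 to 0.31), Cckar (-0.40 to 0.085), Mki67 (-0.14 to 0.097), Npm1 (-0.043 to 0.19), Rps6 (-0.041 to 0.036), Insig1 (-0.27 to 0.45), Atp5b (-0.20 to 0.030), Lyz2 (-0.74 to 0.038), Csf3r (-0.00295 to 0.00542), Ighm (-2.35 to 1.13), Tnfrsf13c (-0.024 to 1.01), Cd4 (-0.22 to 0.75), Lyve1 (-0.46 to 0.41), Car3 (-1.20 to 0.76), Anpep (-0.013 to 0.32) and Ddit4 (-0.025 to 0.061). The list medians that changed sign were digestive enzymes (-0.24 to 0.24), acinar transcription factors (-0.26 to 0.19), ER chaperones (-0.11 to 0.37), ATF4 targets (-0.24 to 0.15), Reg family (-0.040 to 0.044), mitosis (-0.082 to 0.000405), ribosome biogenesis (-0.097 to 0.031), cholesterol synthesis (-0.26 to 0.034), immediate early genes (-0.14 to 0.098), macrophages (-0.34 to 0.31), B and plasma cells (-0.42 to 0.69), adipocytes (-0.31 to 0.57), intestinal epithelium (-0.15 to 0.085) and, without a turn of the test, neutrophils (-0.013 to 0.21), while for oxidative phosphorylation (-0.16 to 0), stellate cells (-0.44 to -0.0025) and mast cells (0.024 to 0.16) the median did not cross 0 and only the direction of the test turned. The pseudocount alternative was not run, since the values are on a log scale, nor trend and robust eBayes for lists; control probes were not told apart among all rows.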

Other observations

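The tests below of glucocorticoid exposure and harvest hour used gene sets fixed before those sets were looked at, but the pattern they test was noticed in the data.

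Immunoglobulin transcripts differed widely between the arrays. Ighg3, chosen after its values were seen, was at 4.26 and 3.89 in wild type and at 8.73 and 7.33 in the null, at least 15.5-fold higher (3.96 ± 0.50 on the log2 scale, SE, a lower bound since the wild-type values lay near the array median, where signal above background is not shown; limma adjusted p = 0.721). Of 22 immunoglobulin rows, 16 were higher and 6 lower in the null, and 1 had an unadjusted p under 0.05; against the wild-type mean, Ifrd1 null 1 was higher in 19 rows and Ifrd1 null 2 in 3, with 19 lower. Mir1938, whose locus lies within Ifrd1, was at -1.14 ± 0.19 (chosen after its values were seen). Of the 100 genes nearest to Ifrd1 in gene order, 8 had an unadjusted p under 0.05, and Mir1938 is counted among these 8. The share was 8%, against 6.90% of the others (odds ratio 1.17, interval 0.491 to 2.42, Fisher's exact test, two-sided p = 0.690).

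Fkbp5 and Zbtb16, both glucocorticoid-induced, were higher in the null, as was Per1 (0.78 ± 0.13, chosen after its values were seen). One hypothesis is higher glucocorticoid exposure of the null mice. A set of 15 further glucocorticoid-induced genes had a median of 0.09, at percentile 99.74 of matched random lists, with 11 of 15 higher; Tsc22d3 (0.52 ± 0.18), Pdk4 (0.50 ± 0.11) and Sgk1 (0.43 ± 0.12) were higher, while Angptl4 (-0.51 ± 0.18) and Lpin1 (-0.50 ± 0.11) went the other way. A different hour of harvest stays open. The medians of the Dbp arm and Bmal1 arm of the clock genes differed by 0.0453 log2 units (interval -0.244 to 0.238, bootstrap over genes, not arrays). The Dbp arm went both ways, with 5 genes higher and 4 lower and Dbp itself at -0.40 ± 0.12. The shift may reflect hormone exposure or harvest hour, and the sex of the mice, which could alter it, cannot be separated from genotype here.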
